A study of Mus musculus with 8 samples.

How the data were processed

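RNA was measured in kidneys of adult male C57BL/6 mice in 8 libraries, 2 in each of WT, KO, WT_IR and KO_IR, and each library pools the RNA of 3 mice per the labels. Libraries were selected for polyadenylated RNA per the labels. The authors deposited FPKM values, fragments per kilobase of gene length scaled by the size of the library, for 54251 genes, after alignment with HISAT2 2.0.5 to the mouse genome (mm10, GRCm38.p6). The tool that counted fragments, the annotation release and the tool that made the FPKM are not given in the sources used here. FPKM times gene length in kb was checked to be a whole multiple of 1 step per library for 100% of the genes in each library (tolerance 1e-06), so the fragments per gene were recovered, 14965700 to 17596700 per library. The denominator that the step implies is 1.18 and 1.19 times the gene total in the WT_IR libraries and 0.921 to 1.03 times in the others. A further scaling that goes with this group is thus already in the deposited values. On a gene of 1 kb 3 fragments correspond to 0.148 to 0.206 FPKM, a floor that covers counting error only.

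The choices in this paragraph were made before the data were examined. Genes with a mean of at least 0.5 FPKM over all libraries were tested (15607), on log2 of FPKM with a pseudocount of 1, so that values of genes near 0 FPKM depend on the pseudocount. All 8 libraries were fitted together in limma 3.58.1 (R 4.3.3) with 1 mean per group and a mean-variance trend, which leaves 4 residual degrees of freedom and adds 3.04 from the prior. The comparisons were WT_IR minus WT, KO_IR minus KO, KO minus WT, KO_IR minus WT_IR, their interaction, and the effects of IR and of the knockout averaged over the other factor. P-values of limma were adjusted by Benjamini-Hochberg within each of the 7 comparisons, with a threshold of 0.05 and no limit on the fold. Errors of log2 changes are standard errors from the fit, and FPKM means are given with the SD of 2 libraries. The number in a library's name was not used as a pairing, because the labels do not say that equal numbers share mice or a day. The responses of the genotypes were compared across genes called by the averaged IR effect, by Pearson's r and a major-axis slope. This axis passes through the means of both responses.

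Lists were tested with camera in limma at a preset correlation of 0.01, adjusted over all lists of a comparison, where at least 3 genes were measured, and again with an estimated correlation. The 19 lists were tubular injury, fatty acid oxidation, oxidative phosphorylation, cell cycle, p53 response, extracellular matrix and fibrosis, chemokines and NF-kB targets, interferon-stimulated genes, glutathione, iron and oxidative stress, ER stress and amino acid response, hypoxia and glycolysis, cholesterol synthesis, autophagy and lysosome, H3K9 and DNA methylation machinery, germline genes, imprinted genes, kidney protective factors, male-biased kidney genes and female-biased kidney genes. The 16 cell type sets were proximal tubule, thick ascending limb, distal convoluted tubule, collecting duct principal cells, intercalated cells, podocytes, endothelium, fibroblasts and pericytes, macrophages, neutrophils, T and NK cells, B cells, red blood cells, adrenal gland, adipose tissue and sex chromosome genes. No gene is in more than 1 of them. The number of members that passed is given over all genes tested and adjusted over the list alone.

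The named genes follow a rule. Ehmt2, Havcr1, Lcn2 and Kl are always given. For each of the first 5 comparisons up to 12 rising and 12 falling protein-coding genes are named, those with the largest fold among genes with an adjusted p under 0.05, libraries of the 2 groups that do not overlap (not asked of the interaction), a mean of at least 2 FPKM in the higher group and a symbol that is not a clone or model number. For each list 2 to 4 members with the smallest p of the comparison are given. 1 list member is not reported here. Clock genes, immediate early genes and mitochondrially encoded genes were chosen after their values were seen.

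Other settings fixed at the same time as the comparisons were a pseudocount of 0.1 or 5, no filter or a minimum mean of 5 FPKM, a TPM scale, median-of-ratios factors, quantile normalization, limma without the trend, robust or with array weights, the replicate number as a block, voom on recovered fragments, only the 2 groups of a comparison, a fold of at least 2, an estimated correlation, and leaving out each library in turn. After seeing the data, fits without KO replicate 2 and KO_IR replicate 1, with a block within genotype, and with a clock gene index as a covariate were added. A fit that leaves out a library leaves its group with 1, which is then assumed to vary like the other groups. The steps were tested on simulated data of 15607 genes with 50 changed genes at each size. For KO after IR 18, 45, 50 and 50 of these were recovered at changes of 1.5, 2, 4 and 8-fold, for IR in KO 21, 44, 50 and 50, and for the interaction 2, 31, 50 and 50. Of 15387 unchanged genes 9, 14 and 7 were called. The simulation gave all genes 1 dispersion (0.0057) and placed the changes in KO_IR only, all upward. Real genes and libraries differ in spread, so these numbers hold for that setting and not for the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.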

Results

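Polyadenylated RNA of kidneys from adult male C57BL/6 mice was sequenced in 8 libraries that fall into 4 groups of 2. WT is wild type and KO is, per the labels, a kidney-specific knockout of Ehmt2, the gene of the histone methyltransferase G9a. WT_IR and KO_IR are the same genotypes after renal ischemia-reperfusion (IR), in which the left renal pedicle was clamped for 45 min and the kidneys were taken on day 3. Each library pools the RNA of 3 mice, so the spread between replicates is a spread between pools. The labels do not say whether the WT and KO libraries come from mice without surgery or from the non-injured kidney of operated mice, nor at which hour of the day the kidneys were taken. The fragments recovered per library from the FPKM values and gene lengths were 17596700 in WT replicate 1, 16584600 in WT replicate 2, 15408300 in KO replicate 1, 16858800 in KO replicate 2, 14965700 in WT_IR replicate 1, 17020900 in WT_IR replicate 2, 17473400 in KO_IR replicate 1 and 15158100 in KO_IR replicate 2. At these depths 3 fragments on a gene of 1 kb correspond to 0.148 to 0.206 FPKM. Of 54251 genes in the file, 15607 passed the filter on low values and were tested. Pearson's r of log2 values across these genes, which are not independent replicates, was 0.985 between the 2 libraries in each of WT, KO and WT_IR and 0.982 in KO_IR. It was 0.897 to 0.908 between WT and WT_IR libraries and 0.974 to 0.982 between KO and KO_IR libraries. On the first principal component, which holds 67.6% of the variance, the WT_IR libraries lay at 60.8 and 63.6. The KO_IR libraries lay at -5.54 and -0.906, between these and the WT and KO libraries at -33.1 to -26.0.

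The knockout was first looked at in Ehmt2, the gene deleted per the labels. Ehmt2 (ENSMUSG00000013787, GRCm38 chromosome 17, 34898469 to 34914052) encodes G9a, which methylates lysine 9 of histone H3. Its level was 33.4 and 30.3 FPKM in the WT libraries, 28.1 and 26.4 in KO, 34.5 and 35.8 in WT_IR and 27.3 and 26.3 in KO_IR. The KO mean was 85.4% of the WT mean, and the KO_IR mean was 76.2% of the WT_IR mean. The log2 difference was -0.22 ± 0.083 (SE, n = 2, adjusted p = 0.370 by limma) without IR, which did not pass, and -0.38 ± 0.083 (adjusted p = 0.0140) after IR. The call after IR ended without WT_IR replicate 1, WT_IR replicate 2 or KO_IR replicate 2. The value covers the whole gene model and the whole kidney, so it does not separate deleted exons, or cells in which the deletion took place, from the rest. These values do not show the deletion, and the genotype is taken from the labels. With IR itself Ehmt2 changed by 0.14 ± 0.083 in WT (adjusted p = 0.227) and by -0.022 ± 0.083 in KO (adjusted p = 0.951).

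**Figure D1:**
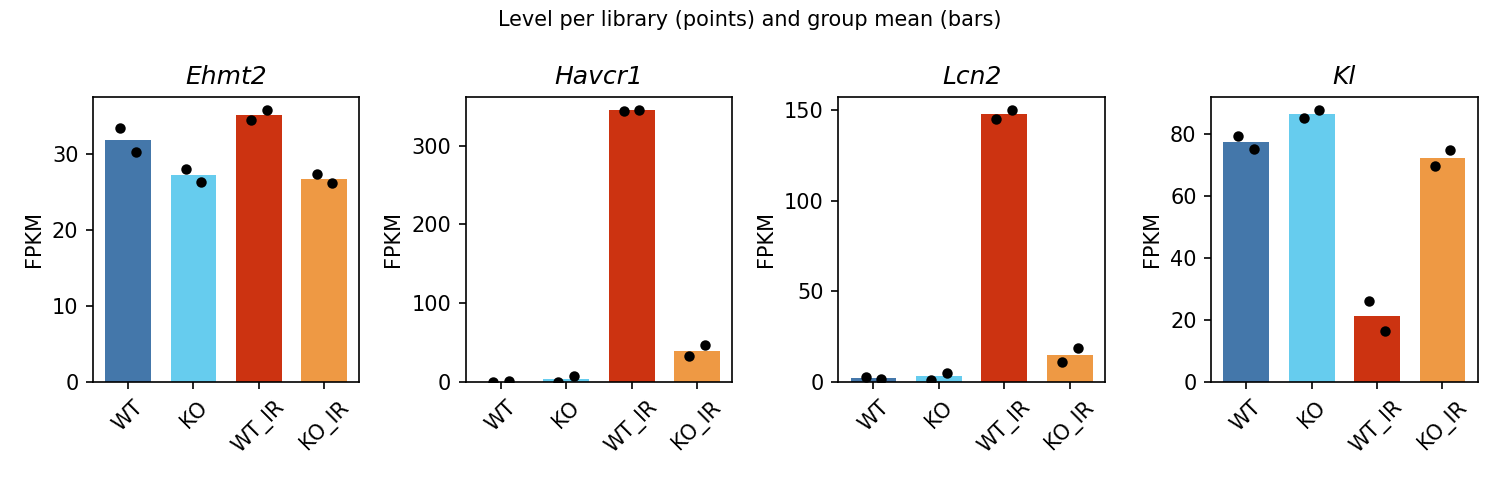
Level in FPKM (vertical axes, linear, from 0) of Ehmt2 and of 3 kidney genes fixed in advance, in the 4 groups, with bars for group means and points for the 2 libraries of each group. Havcr1 stands at 344 FPKM in WT_IR and 40.2 in KO_IR, and Kl at 21.3 in WT_IR and 72.2 in KO_IR.

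The comparison of WT_IR with WT asks what ischemic injury does to the wild-type kidney by day 3. The largest rises included genes of tubular injury, inflammation and matrix. Havcr1 (ENSMUSG00000040405, GRCm38 chromosome 11, 46735080 to 46779578), which encodes the injury marker KIM-1, went from 1.03 ± 0.286 to 344 ± 0.557 FPKM (SD, n = 2), a log2 change of 7.42 ± 0.67 (SE, adjusted p = 0.000218). Lcn2 (ENSMUSG00000026822, GRCm38 chromosome 2, 32384633 to 32388252), the gene of NGAL, went from 2.39 ± 0.618 to 147 ± 3.37 FPKM, a log2 change of 5.47 ± 0.41 (adjusted p = 0.000120). On the log2 scale complement C3 rose by 5.48 ± 0.25, the adhesion molecule gene Vcam1 by 5.10 ± 0.22 and the fibrillar collagen gene Col3a1 by 5.03 ± 0.27. The other largest rises, those of Col1a1, Timp1, Krt20, Serpina10, Ccl2, Aoc1 and Cxcl10, were 4.29 to 4.76. The largest falls included Egf and genes of calcium-binding proteins. Egf, a growth factor of the distal nephron, went from 173 ± 0.971 to 7.16 ± 2.20 FPKM, a log2 change of -4.44 ± 0.18 (adjusted p = 4.59e-05). Of the calcium-binding proteins, Pvalb changed by -4.27 ± 0.14, Calb1 by -4.14 ± 0.21 and S100g by -3.98 ± 0.19. Pvalb in WT_IR (0.0473 ± 0.0669 FPKM, SD) and Timp1 (0.0712 ± 0.00239) and Ccl2 (0.0542 ± 0.0767) in WT were near 0. The log2 changes of these 3 genes, here and in other comparisons with these groups, thus depend in size on the pseudocount of 1. The organic anion transporter gene Slc22a8 changed by -4.11 ± 0.18 and the kallikrein gene Klk1 by -3.61 ± 0.12. The log2 changes of Ttr, Nccrp1, Inmt, Hpd, Ces1d and mt-Co3 were -3.27 to -4.03, and reads of Ces1d and mt-Co3 can be shared with close paralogs or neighbouring transcripts. Kl (ENSMUSG00000058488, GRCm38 chromosome 5, 150952607 to 150993817), the gene of klotho, went from 77.3 ± 2.91 to 21.3 ± 6.91 FPKM, a log2 change of -1.85 ± 0.19 (adjusted p = 0.000342). In all, limma called 2980 genes higher and 3616 lower, 2203 of them by at least 2-fold. On a TPM scale, which shifts the median of all genes by 0.387 on the log2 scale, 7537 rose and 1541 fell. With a minimum mean of 5 FPKM 1312 rose and 2922 fell.

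Lists of genes fixed in advance describe this response by function, starting with injury and inflammation. In the tubular injury list 17 of 18 measured genes rose (17 adjusted over the list alone, adjusted p = 7.85e-12), and the hyaluronan receptor gene Cd44 changed by 3.82 ± 0.16 and the keratin gene Krt20 by 4.57 ± 0.19. In the extracellular matrix and fibrosis list 20 of 20 measured genes rose (20 adjusted over the list alone, adjusted p = 7.85e-12), led by Col1a1 (4.75 ± 0.22) and Col3a1. Of chemokines and NF-kB targets 19 of 19 measured genes rose (19 adjusted over the list alone, adjusted p = 1.60e-13), among them Il34, a growth factor of macrophages, at 2.88 ± 0.12, beside Vcam1. Of interferon-stimulated genes 19 of 20 measured genes rose (20 adjusted over the list alone, adjusted p = 1.66e-11). Ddx58, which encodes the RNA sensor RIG-I, changed by 1.49 ± 0.077 and Zbp1 by 1.87 ± 0.097. Cell cycle transcripts were higher too, as 23 of 25 measured cell cycle genes rose (24 adjusted over the list alone, adjusted p = 7.71e-11). Top2a changed by 1.43 ± 0.12 and Mki67 by 1.39 ± 0.11. In the ER stress and amino acid response list 9 of 14 measured genes rose and 1 fell (11 and 2 adjusted over the list alone, adjusted p = 0.00181). Trib3 changed by 2.29 ± 0.13 and Asns by 1.46 ± 0.13. Of the H3K9 and DNA methylation machinery, which includes partners of G9a, 6 of 19 measured genes rose (6 adjusted over the list alone, adjusted p = 0.0240). Uhrf1 changed by 1.57 ± 0.21 and the demethylase gene Kdm4a by 0.85 ± 0.12. With an estimated correlation in place of the preset one none of these 7 lists was called, at adjusted p = 0.192 to 0.205. The p53 response list did not pass, as 6 of 15 measured genes rose and 2 fell (8 and 2 adjusted over the list alone, adjusted p = 0.0582). Bbc3 changed by 1.79 ± 0.23 and Phlda3 by 1.52 ± 0.30.

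Markers of infiltrating and stromal cells rose with the injury. For macrophages 12 of 12 measured markers rose (12 adjusted over the list alone, adjusted p = 4.79e-10), with the complement gene C1qb at 3.36 ± 0.15 and the Fc receptor gene Fcgr1 at 2.69 ± 0.12. For fibroblasts and pericytes 6 of 6 measured markers rose (6 adjusted over the list alone, adjusted p = 0.000407). Pdgfrb changed by 2.37 ± 0.14 and Dcn by 1.92 ± 0.25. For T and NK cells 6 of 6 measured markers rose (6 adjusted over the list alone, adjusted p = 0.000968). Cd2 changed by 1.04 ± 0.14 and Nkg7 by 2.09 ± 0.28. For neutrophils 3 of 5 measured markers rose (3 adjusted over the list alone, adjusted p = 0.0153). Csf3r changed by 1.40 ± 0.16 and Mmp9 by 1.30 ± 0.20. Red blood cell transcripts fell, as 4 of 5 measured markers fell (4 adjusted over the list alone, adjusted p = 0.0399). The alpha-globin genes Hba-a1 and Hba-a2, whose reads can be shared, changed by -0.97 ± 0.17 and -1.31 ± 0.31. That call ended without WT replicate 2 or WT_IR replicate 1, and Hba-a2 no longer passed without WT replicate 1, WT replicate 2 or WT_IR replicate 1. For these 5 sets an estimated correlation gave adjusted p = 0.192 to 0.420. Endothelial markers did not pass as a set, as 6 of 10 measured markers rose and 1 fell (6 and 1 adjusted over the list alone, adjusted p = 0.106). Cdh5 changed by 0.86 ± 0.12 and Pecam1 by 0.74 ± 0.15. Podocyte markers did not pass either, as 3 of 7 measured markers fell and 1 rose (3 and 1 adjusted over the list alone, adjusted p = 0.493). Podxl changed by -0.61 ± 0.099 and Synpo by 0.52 ± 0.10. Of 4 sex chromosome genes 0 passed, also adjusted over the list alone (adjusted p = 0.988), and their median of 0.012 and mean of -0.014 differ in sign.

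Lists of energy metabolism genes and markers of several tubular cell types fell in WT. The libraries hold RNA of the whole kidney, so marker levels do not separate the number of cells from the level per cell. Of oxidative phosphorylation genes 22 of 22 measured genes fell (22 adjusted over the list alone, adjusted p = 1.11e-12). Atp5a1 changed by -1.41 ± 0.082 and Uqcrc2 by -1.32 ± 0.082. Of fatty acid oxidation genes 21 of 22 measured genes fell (21 adjusted over the list alone, adjusted p = 7.70e-10). The acyl-CoA dehydrogenase gene Acads changed by -1.42 ± 0.089 and the thiolase gene Acaa2 by -1.96 ± 0.14. In the proximal tubule 16 of 16 measured markers fell (16 adjusted over the list alone, adjusted p = 4.38e-09), with the glucose transporter gene Slc5a2 at -1.93 ± 0.12 beside Slc22a8. In the distal convoluted tubule, led by Pvalb and Calb1, 5 of 5 measured markers fell (5 adjusted over the list alone, adjusted p = 0.000276). Of intercalated cell markers 4 of 6 measured genes fell (4 adjusted over the list alone, adjusted p = 0.00423), with the anion exchanger genes Slc26a4 at -2.31 ± 0.12 and Slc4a1 at -3.01 ± 0.25. In the thick ascending limb 4 of 6 measured markers fell (5 adjusted over the list alone, adjusted p = 0.0153). Kcnj1 changed by -1.65 ± 0.13 and Slc12a1 by -1.90 ± 0.20. Of kidney protective factors 6 of 8 measured genes fell (6 adjusted over the list alone, adjusted p = 0.00261), with the deacetylase gene Sirt3 at -1.31 ± 0.085 beside Egf. Of male-biased kidney genes 9 of 12 measured genes fell and 1 rose (10 and 1 adjusted over the list alone, adjusted p = 0.000710). Nudt19 changed by -1.42 ± 0.11 and Slc7a13 by -3.21 ± 0.25. An estimated correlation gave adjusted p = 0.192 to 0.391 for these 8 lists. Collecting duct principal cells did not pass as a set, as 2 of 5 measured markers fell (2 adjusted over the list alone, adjusted p = 0.0872). The water channel gene Aqp3 changed by -1.52 ± 0.19 and Scnn1g by -0.42 ± 0.12, and the sign of Scnn1g turned on a TPM scale. Scnn1g no longer passed without WT replicate 1, WT_IR replicate 1 or WT_IR replicate 2. Nor did female-biased kidney genes pass, of which 4 of 6 measured genes fell and 1 rose (4 and 1 adjusted over the list alone, adjusted p = 0.184). Abcc3 changed by 1.81 ± 0.15 and Cyp2a4 by -2.41 ± 0.32.

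Other metabolic lists fell by less. In the hypoxia and glycolysis list 10 of 15 measured genes fell and 1 rose (10 and 1 adjusted over the list alone, adjusted p = 0.00451), with the glycolytic gene Pgk1 at -1.05 ± 0.091 and the hexokinase gene Hk2 at 1.56 ± 0.14. In the glutathione, iron and oxidative stress list 11 of 19 measured genes fell and 2 rose (12 and 3 adjusted over the list alone, adjusted p = 0.0130). Ggt1 changed by -1.85 ± 0.12 and Gss by -1.02 ± 0.10. Of cholesterol synthesis genes 7 of 16 measured genes fell and 1 rose (7 and 1 adjusted over the list alone, adjusted p = 0.0148). Cyp51 changed by -1.94 ± 0.15 and Nsdhl by -1.06 ± 0.12. For these 3 lists an estimated correlation gave adjusted p = 0.192 to 0.440. Autophagy and lysosome genes did not pass as a set, as 7 of 15 measured genes fell and 2 rose (7 and 2 adjusted over the list alone, adjusted p = 0.240). Ctsd changed by 1.05 ± 0.096 and Gabarapl1 by -1.22 ± 0.16. Imprinted genes did not pass either, as 3 of 11 measured genes rose and 3 fell (3 and 3 adjusted over the list alone, adjusted p = 0.684). Snrpn changed by -0.85 ± 0.13 and Ndn by 0.99 ± 0.17. Sets with fewer than 3 measured genes were not tested. Of germline genes Sycp3 alone was measured (-0.84 ± 0.20), of B cell markers Cd79b (1.12 ± 0.26) and of adrenal gland markers Star (-0.13 ± 0.13, adjusted p = 0.463). Of adipose tissue markers none was measured, and their highest FPKM in any library was 0.374. Sycp3 no longer passed without WT replicate 2 or WT_IR replicate 2, and Cd79b without WT replicate 1 or WT_IR replicate 1.

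**Figure D2:**
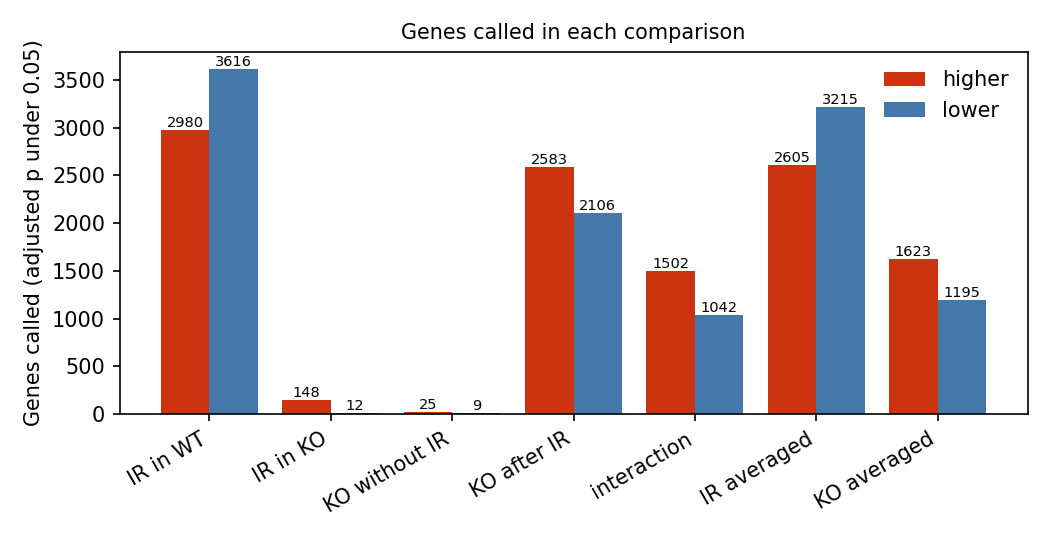
Number of genes called by limma at an adjusted p under 0.05 (vertical axis, linear) in each of the 7 comparisons (horizontal axis), with higher and lower genes as separate bars. IR called 6596 genes in WT and 160 in KO, and the knockout 34 without IR and 4689 after IR.

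The comparison of KO_IR with KO asks the same of the KO kidneys. Collagen and other matrix transcripts and C3 rose, and Col3a1 went from 2.22 ± 1.42 to 26.5 ± 2.18 FPKM (SD, n = 2), a log2 change of 3.17 ± 0.27 (SE, adjusted p = 0.0143). Col1a1 changed by 3.09 ± 0.22, Col1a2 by 2.06 ± 0.19 and C3 by 2.31 ± 0.25. Timp1, an inhibitor of matrix metalloproteinases, rose by 2.22 ± 0.21 and Vcam1 by 1.85 ± 0.22. The other largest rises, those of Cpe, Fn1, Krt20, Serpina10, Fcer1g and Ccnb2, were 1.65 to 1.98. Few genes fell, among them the steroid hydroxylase gene Cyp7b1 at -1.70 ± 0.26 and the alpha-1-antitrypsin gene Serpina1d, which has close paralogs, at -1.69 ± 0.24. The values of Sec14l3, C8a, Itih2, Mettl7a2, Akr1c14, Pvalb and Alb were -0.83 to -1.09. Havcr1 stood at 0.593 and 7.5 FPKM in the KO libraries and at 33.1 and 47.3 in KO_IR, and its log2 change of 3.46 ± 0.67 did not pass (adjusted p = 0.0706). Nor did those of Lcn2 (1.97 ± 0.41, adjusted p = 0.0868) and Kl (-0.26 ± 0.19, adjusted p = 0.648). In all 148 genes rose and 12 fell, 92 of them by at least 2-fold. Of the risers 143 also rose in WT (28.3 if the calls were independent), and of the 12 that fell 10 also fell in WT (2.78 if independent). Both sets of calls share 1 fit and its estimate of spread, so they are not independent. In limma 0 genes passed without WT_IR replicate 1, WT_IR replicate 2 or KO_IR replicate 1, with 1825, 1829 and 1879 at an unadjusted p under 0.05, against 1991 with all libraries. Without KO replicate 1 the count was 5, without WT replicate 2 79, without WT replicate 1 82 and without KO_IR replicate 2 97. With only the 2 groups in the limma fit 0 passed (1806 unadjusted), without the filter on low values 35, and with voom on recovered fragments 314.

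Of the lists, 10 sets were called upward in KO, among them injury, matrix, cell cycle and macrophage genes. In the tubular injury list, led by Timp1 and Krt20, 6 of 18 measured genes rose (15 adjusted over the list alone, adjusted p = 5.08e-20). In the matrix list, led by Col1a1 and Col3a1, 8 of 20 measured genes rose (16 adjusted over the list alone, adjusted p = 4.95e-20). Of cell cycle genes 7 of 25 measured genes rose (16 adjusted over the list alone, adjusted p = 4.95e-20), with the cyclin gene Ccnb2 at 1.65 ± 0.16 and Mki67 at 1.09 ± 0.11. Of chemokines and NF-kB targets, led by C3 and Vcam1, 4 of 19 measured genes rose (16 adjusted over the list alone, adjusted p = 1.02e-18). Among interferon-stimulated genes 5 of 20 measured genes rose (17 adjusted over the list alone, adjusted p = 5.22e-17). Zbp1 changed by 0.83 ± 0.097 and Oas1a by 0.80 ± 0.11. Macrophage markers rose, as 7 of 12 measured genes rose (11 adjusted over the list alone, adjusted p = 1.68e-18). Fcgr1 changed by 1.47 ± 0.12 and C1qb by 1.63 ± 0.15. Fibroblast and pericyte markers were called upward as a set, and 1 of 6 measured genes rose (6 adjusted over the list alone, adjusted p = 2.15e-06). Pdgfrb changed by 0.97 ± 0.14 and Lum by 0.82 ± 0.16. A further 3 sets were called upward with 0 single genes passing over all genes. They were T and NK cells (0 rising adjusted over the list alone, adjusted p = 0.00674), with Nkg7 at 0.86 ± 0.28 and Lck at 0.58 ± 0.23, and the ER stress and amino acid response (0 rising adjusted over the list alone, adjusted p = 0.00559), with Sdf2l1 at 0.51 ± 0.14 and Atf3 at 3.10 ± 1.00. The last was the p53 response (0 rising adjusted over the list alone, adjusted p = 0.0445), with Plk2 at 0.56 ± 0.17 and Bbc3 at 0.64 ± 0.23. Atf3 stood at 60.2 FPKM in KO_IR replicate 1 and 3.72 in KO_IR replicate 2, and the p53 list genes Btg2 and Gdf15, named here after their values were seen, at 73.6 and 10.2 and at 63.6 and 11.0. An estimated correlation gave these 10 upward sets adjusted p = 0.111 to 0.535.

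Sets called downward in KO had few or no single genes that passed. The median log2 change of distal convoluted tubule markers was -0.40 (1 of 5 fell, 2 adjusted over the list alone, adjusted p = 0.000358), with Pvalb at -0.84 ± 0.14 and Calb1 at -0.63 ± 0.21. That of oxidative phosphorylation was -0.18 (0 of 22 fell, 0 adjusted over the list alone, adjusted p = 1.13e-05). Atp5a1 changed by -0.30 ± 0.082 and Uqcrc2 by -0.25 ± 0.082. For fatty acid oxidation it was -0.21 (0 of 22 fell, 0 adjusted over the list alone, adjusted p = 3.23e-05). Acads changed by -0.36 ± 0.089 and Acadm by -0.53 ± 0.13. For the proximal tubule it was -0.15 (0 of 16 fell, 0 adjusted over the list alone, adjusted p = 0.0287). Aqp1 changed by -0.44 ± 0.17 and Slc22a8 by -0.39 ± 0.18. For the thick ascending limb it was -0.42 (0 of 6 fell, 1 adjusted over the list alone, adjusted p = 0.0121). Kcnj1 changed by -0.56 ± 0.13 and Slc12a1 by -0.55 ± 0.20. For red blood cells it was -0.60 (0 of 5 fell, 3 adjusted over the list alone, adjusted p = 0.000930). Hba-a1 changed by -0.68 ± 0.17 and Alas2 by -0.56 ± 0.16. An estimated correlation gave adjusted p = 0.312 to 0.565 for these 6. The other 15 sets tested were not called, and in the H3K9 machinery and podocyte sets, whose adjusted p were 0.970 and 0.809, the median and the test differ in sign. Leaving out KO replicate 1 ended the calls of p53 response, ER stress and proximal tubule, and leaving out KO_IR replicate 2 those of p53 response, proximal tubule, fatty acid oxidation and T and NK cells. Without KO replicate 2 the thick ascending limb and red blood cells were not called, without KO_IR replicate 1 the thick ascending limb, and without WT replicate 1 or WT replicate 2 the p53 response.

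The comparison of KO with WT asks what differs between the genotypes without IR. Interferon-induced genes were among the risers, and Ifit3b, which has close paralogs, went from 2.82 ± 0.240 to 8.10 ± 0.129 FPKM (SD, n = 2), a log2 change of 1.25 ± 0.11 (SE, adjusted p = 0.0444). Rtp4 rose by 1.11 ± 0.12, Oasl2 by 1.10 ± 0.11, the interferon regulatory factor gene Irf7 by 1.08 ± 0.12 and Oas2 by 1.04 ± 0.13. Other risers were Slc7a12, a transporter gene higher in female kidneys, at 1.92 ± 0.16, the prolactin receptor gene Prlr at 1.16 ± 0.14 and the clock repressor gene Ciart at 1.61 ± 0.19. Sycn rose by 2.47 ± 0.26, Defb42 by 1.47 ± 0.18, Ces1g by 1.28 ± 0.12 and Slamf9 by 0.97 ± 0.11. Proliferation genes fell, with the ribonucleotide reductase gene Rrm2 at -1.5 ± 0.16, Ccnb2 at -1.44 ± 0.16 and Ube2c at -1.07 ± 0.13. Ndrg1 went from 541 to 201 FPKM (-1.42 ± 0.18), and the complement gene C4b changed by -1.26 ± 0.14 and Prr5 by -0.99 ± 0.13. In all 25 genes rose and 9 fell, with adjusted p of 0.0419 or more, and 1854 had an unadjusted p under 0.05. Havcr1 (0.87 ± 0.67, adjusted p = 0.665), Lcn2 (0.23 ± 0.41, adjusted p = 0.863) and Kl (0.16 ± 0.19, adjusted p = 0.794) did not pass. KO replicate 2 held more of several injury transcripts than KO replicate 1, with Havcr1 at 7.5 against 0.593 FPKM, Lcn2 at 5.13 against 1.54 and Timp1 at 0.843 against 0.154. In limma 0 genes passed without WT replicate 1 or KO replicate 1 (1635 and 1407 at an unadjusted p under 0.05), and 1 without WT replicate 2 or KO replicate 2. Without WT_IR replicate 1 or WT_IR replicate 2 the count was 5, and without KO_IR replicate 1 or KO_IR replicate 2 17. Quantile normalization (1757 unadjusted) and a limma fit of only the 2 groups (1755 unadjusted) also gave 0, a pseudocount of 5 gave 7, the replicate number as a block 9, and voom 61.

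As sets, interferon-stimulated genes were called upward and cell cycle genes downward in KO. In the interferon list, led by Oasl2 and Irf7, 5 of 20 measured genes rose (20 adjusted over the list alone, adjusted p = 3.92e-25), with a median log2 change of 0.74. In the cell cycle list, led by Rrm2 and Ccnb2, 3 of 25 measured genes fell (17 adjusted over the list alone, adjusted p = 1.65e-17), with a median of -0.58. Female-biased genes were called upward, as 2 of 6 measured genes rose (2 adjusted over the list alone, adjusted p = 0.00783), Slc7a12 and Prlr. For the next 5 sets 0 genes passed over all genes. Macrophage markers had a median of 0.42 (4 rising adjusted over the list alone, adjusted p = 1.25e-05), with C1qc at 0.69 ± 0.15 and C1qa at 0.51 ± 0.15. Endothelial markers had a median of 0.28 (5 rising adjusted over the list alone, adjusted p = 7.01e-06), with Kdr at 0.47 ± 0.097 and Tek at 0.42 ± 0.12. Cholesterol synthesis had a median of 0.29 (1 rising adjusted over the list alone, adjusted p = 2.64e-05), with Cyp51 at 0.74 ± 0.15 and Dhcr7 at 0.40 ± 0.10. Fatty acid oxidation had a median of -0.34 (2 falling adjusted over the list alone, adjusted p = 1.57e-06), with Slc25a20 at -0.66 ± 0.13 and Hadha at -0.35 ± 0.082. Oxidative phosphorylation had a median of -0.21 (1 falling adjusted over the list alone, adjusted p = 2.77e-06), with Cycs at -0.44 ± 0.080 and Atp5d at -0.36 ± 0.12. Autophagy and lysosome (adjusted p = 0.00366), with Tfeb at -0.28 ± 0.086 and Gabarap at -0.24 ± 0.088, and p53 response (adjusted p = 0.0446), with Cdkn1a at -0.96 ± 0.41 and Sesn2 at -0.30 ± 0.13, were called downward. Chemokines and NF-kB targets (adjusted p = 0.0494), with Cxcl10 at 1.00 ± 0.29 and Ccl2 at 0.67 ± 0.22, were called upward, and in these last 3 sets 0 single genes passed, also adjusted over the list alone. An estimated correlation left none of the 11, with adjusted p = 0.121 to 0.690. The chemokine list was lost without WT replicate 1 or KO replicate 2, p53 response without WT replicate 2 or KO replicate 1, and autophagy without WT replicate 2.

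The comparison of KO_IR with WT_IR sets the genotypes against each other after the injury. Among genes higher in KO_IR, Egf stood at 179 ± 12.9 against 7.16 ± 2.20 FPKM (SD, n = 2), a log2 difference of 4.49 ± 0.18 (SE, adjusted p = 0.000152). The methyltransferase gene Inmt differed by 4.24 ± 0.28, Slc22a8 by 4.11 ± 0.18 and the tyrosine catabolism gene Hpd by 3.75 ± 0.54. The other largest positive differences, those of Nccrp1, S100g, Slc7a13, Klk1, Cyp2d12, Ttr, Ces1e and Ces1d, were 3.26 to 3.49. Among genes lower in KO_IR, Havcr1 stood at 40.2 ± 10 against 344 ± 0.557 FPKM, a log2 difference of -3.09 ± 0.67 (adjusted p = 0.0133). Lcn2 stood at 15.0 ± 5.58 against 147 ± 3.37 FPKM (-3.26 ± 0.41, adjusted p = 0.00175). C3 differed by -3.25 ± 0.25, the progenitor transcription factor gene Sox9 by -3.11 ± 0.18 and Vcam1 by -3.00 ± 0.22. The other largest negative differences, which include fibrinogen chains, a heat shock gene and Tlr2, were -2.65 to -2.81 for Fgg, Serpina3n, Fga, Prrg4, Hspb1, Tlr2 and Krt20. Kl was higher in KO_IR, 72.2 ± 3.72 against 21.3 ± 6.91 FPKM (1.75 ± 0.19, adjusted p = 0.00105). In all 2583 genes were higher and 2106 lower in KO_IR, and 1138 differed by at least 2-fold. On a TPM scale, which shifts the median of all genes by -0.278, 1423 were higher and 6107 lower. With a clock gene index as a covariate, an alternative chosen after seeing the data, 176 passed, while over the 4689 genes the median size of the log2 difference went from 0.69 to 0.60 and the median SE from 0.125 to 0.234. The count was 2612 without WT_IR replicate 2, 2845 without WT_IR replicate 1 and 2989 without KO_IR replicate 1, and Havcr1 ceased to pass without any 1 of these 3. Fga was lost without WT_IR replicate 2 or KO_IR replicate 2.

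Lists of metabolism genes and markers of several tubular cell types were higher in KO_IR. Of oxidative phosphorylation genes 22 of 22 measured genes were higher (22 adjusted over the list alone, adjusted p = 6.70e-13). Sdha differed by 1.2 ± 0.094 and Ndufs1 by 1.27 ± 0.10. Of fatty acid oxidation genes 13 of 22 measured genes were higher (17 adjusted over the list alone, adjusted p = 4.41e-07). Acads differed by 0.99 ± 0.089 and Acaa2 by 1.34 ± 0.14. In the proximal tubule 16 of 16 measured markers were higher (16 adjusted over the list alone, adjusted p = 1.01e-11), with the inositol oxygenase gene Miox at 2.50 ± 0.17 beside Slc22a8. In the distal convoluted tubule 4 of 5 measured markers were higher (4 adjusted over the list alone, adjusted p = 0.000174). Pvalb differed by 2.99 ± 0.14 and Calb1 by 3.00 ± 0.21. Of intercalated cell markers 3 of 6 measured genes were higher (3 adjusted over the list alone, adjusted p = 0.00350). Slc26a4 differed by 1.72 ± 0.12 and Slc4a1 by 2.68 ± 0.25. In the thick ascending limb 2 of 6 measured markers were higher (4 adjusted over the list alone, adjusted p = 0.00643). Kcnj1 differed by 1.30 ± 0.13 and Slc12a1 by 1.56 ± 0.20. Of cholesterol synthesis genes 13 of 16 measured genes were higher (14 adjusted over the list alone, adjusted p = 7.32e-07). Cyp51 differed by 2.05 ± 0.15 and Idi1 by 1.25 ± 0.12. Of kidney protective factors 6 of 8 measured genes were higher (6 adjusted over the list alone, adjusted p = 0.000251), with Sirt3 at 1.03 ± 0.085 beside Egf. These 8 sets were not called with an estimated correlation (adjusted p = 0.205 to 0.343).

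Sex-biased genes were higher in KO_IR in both directions of bias. Of male-biased genes 7 of 12 measured genes were higher and 1 lower (9 and 1 adjusted over the list alone, adjusted p = 0.00111). Slc7a13 differed by 3.40 ± 0.25 and Odc1 by 1.19 ± 0.099. Of female-biased genes 4 of 6 measured genes were higher and 1 lower (4 and 1 adjusted over the list alone, adjusted p = 0.0314). Slc7a12 differed by 2.67 ± 0.16 and Prlr by 1.39 ± 0.14. In the glutathione, iron and oxidative stress list 6 of 19 measured genes were higher and 4 lower (8 and 4 adjusted over the list alone, adjusted p = 0.0464). Ggt1 differed by 1.51 ± 0.12 and Gss by 0.94 ± 0.10. In the hypoxia and glycolysis list 6 of 15 measured genes were higher and 2 lower (6 and 2 adjusted over the list alone, adjusted p = 0.0464). Vegfa differed by 1.02 ± 0.11 and Pgk1 by 0.76 ± 0.091. For these 4 an estimated correlation gave adjusted p = 0.205 to 0.422. The glutathione call was lost when any 1 library other than KO_IR replicate 2 was left out, the hypoxia call without WT_IR replicate 1 or KO_IR replicate 1, and the female-biased call without KO_IR replicate 1.

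The injury, chemokine, cell cycle, matrix and several cell marker lists were lower in KO_IR. Of tubular injury genes 15 of 18 measured genes were lower (15 adjusted over the list alone, adjusted p = 3.30e-09), with Cd44 at -2.44 ± 0.16 beside Sox9. Of chemokines and NF-kB targets 17 of 19 measured genes were lower (18 adjusted over the list alone, adjusted p = 3.30e-12). Il34 differed by -2.41 ± 0.12 and Relb by -1.77 ± 0.10. Of cell cycle genes 24 of 25 measured genes were lower (24 adjusted over the list alone, adjusted p = 1.10e-12). Mki67 differed by -1.19 ± 0.11 and Bub1b by -1.18 ± 0.11. In the matrix list 12 of 20 measured genes were lower (15 adjusted over the list alone, adjusted p = 2.71e-07). The basement membrane collagen genes Col4a2 and Col4a1 differed by -1.03 ± 0.11 and -1.15 ± 0.12. Of macrophage markers 9 of 12 measured genes were lower (10 adjusted over the list alone, adjusted p = 2.21e-06). Cx3cr1 differed by -1.32 ± 0.14 and Cd68 by -1.33 ± 0.15. Of neutrophil markers 3 of 5 measured genes were lower (5 adjusted over the list alone, adjusted p = 0.00505). Csf3r differed by -0.93 ± 0.16 and Mmp9 by -1.05 ± 0.20. Of T and NK cell markers 4 of 6 measured genes were lower (5 adjusted over the list alone, adjusted p = 0.00776). Cd2 differed by -0.69 ± 0.14 and Nkg7 by -1.27 ± 0.28. Of fibroblast and pericyte markers 2 of 6 measured genes were lower (2 adjusted over the list alone, adjusted p = 0.0343). Pdgfrb differed by -1.09 ± 0.14 and Pdgfra by -0.99 ± 0.27. None of these 8 sets was called with an estimated correlation (adjusted p = 0.205 to 0.390).

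The ER stress, p53 and H3K9 machinery lists were lower in KO_IR as well. Of ER stress and amino acid response genes 6 of 14 measured genes were lower and 1 higher (8 and 1 adjusted over the list alone, adjusted p = 0.00111). Trib3 differed by -1.74 ± 0.13 and Asns by -1.58 ± 0.13. Of p53 response genes 5 of 15 measured genes were lower and 1 higher (5 and 1 adjusted over the list alone, adjusted p = 0.0305). Bbc3 differed by -1.56 ± 0.23 and Fas by -0.68 ± 0.14. Of the H3K9 and DNA methylation machinery 7 of 19 measured genes were lower (8 adjusted over the list alone, adjusted p = 0.00833). Kdm4a differed by -0.85 ± 0.12 and Uhrf1 by -1.17 ± 0.21. For these 3 sets an estimated correlation gave adjusted p = 0.205 to 0.422. Interferon-stimulated genes did not pass as a set, as 1 of 20 measured genes was lower (1 adjusted over the list alone, adjusted p = 0.595). Ddx58 differed by -0.58 ± 0.077 and Oas2 by -0.29 ± 0.13. Nor did the other 7 sets tested, and in the autophagy and imprinted lists, whose adjusted p were 0.841 and 0.862, the median and the test differ in sign. The fibroblast call was lost without WT_IR replicate 1 or KO_IR replicate 1, and the p53 call without WT_IR replicate 2 or KO_IR replicate 2. Among the genes named for these lists, Pdgfra was lost without any 1 of KO replicate 1, KO replicate 2, WT_IR replicate 1, WT_IR replicate 2 and KO_IR replicate 1. Fas was lost without WT_IR replicate 1 or KO_IR replicate 1, Mmp9 without WT_IR replicate 1, and Cd2 and Nkg7 without WT_IR replicate 2 or KO_IR replicate 1.

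The interaction asks for which genes the response to IR differed between the genotypes, as the change in KO minus the change in WT. The largest positive values included tubular genes that fell in WT, with Egf at 3.98 ± 0.25 (SE, n = 2 libraries in each of 4 groups, adjusted p = 0.00234), S100g at 3.72 ± 0.26, Slc22a8 at 3.71 ± 0.26 and Klk1 at 3.56 ± 0.17. The other largest positive values, those of Calb1, mt-Atp8, Pvalb, Nccrp1, Ttr, Inmt, Ces1d and mt-Co3, were 3.19 to 3.51. Kl had a value of 1.59 ± 0.27 (adjusted p = 0.0105). The largest negative values included injury and inflammation genes that rose in WT, with Havcr1 at -3.95 ± 0.94 (adjusted p = 0.0320), Lcn2 at -3.49 ± 0.58 and the diamine oxidase gene Aoc1 at -3.46 ± 0.50. Vcam1 had a value of -3.25 ± 0.31, C3 of -3.16 ± 0.36 and Sox9 of -3.13 ± 0.25. The other largest negative values, those of Ccl2, Cxcl10, Prrg4, Hspb1, Krt20 and Cp, were -2.75 to -3.11. For Ehmt2 the value was -0.16 ± 0.12 (adjusted p = 0.407). In all 1502 genes were positive and 1042 negative, 1150 of them by at least 2-fold, and 2540 had the sign opposite to the response in WT. The interaction subtracts the WT response, so noise in the WT and WT_IR libraries alone favours this opposite sign. On a TPM scale, which shifts the median by -0.339, 755 were positive and 4068 negative, and without the filter on low values 1670 passed. The count was 1289 without WT_IR replicate 2, 1293 without KO replicate 2, 1354 without WT replicate 1, 1368 without WT_IR replicate 1 and 1543 without KO_IR replicate 1. Without both KO replicate 2 and KO_IR replicate 1, an alternative chosen after seeing the data, 497 passed.

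The same contrast shows in the lists. The median for the proximal tubule was 1.91, and 13 of 16 measured markers were positive (16 adjusted over the list alone, adjusted p = 5.89e-11), with Miox at 2.62 ± 0.24 beside Slc22a8. For the distal convoluted tubule, led by Pvalb and Calb1, it was 1.43, and 4 of 5 measured markers were positive (4 adjusted over the list alone, adjusted p = 8.99e-05). For oxidative phosphorylation the median was 1.16, and 21 of 22 measured genes were positive (21 adjusted over the list alone, adjusted p = 6.78e-16). Cycs stood at 1.14 ± 0.11 and Atp5a1 at 1.11 ± 0.12. For fatty acid oxidation the median was 0.93, and 13 of 22 measured genes were positive (20 adjusted over the list alone, adjusted p = 1.91e-10). Acaa2 stood at 1.84 ± 0.19 and Acads at 1.06 ± 0.13. For male-biased kidney genes it was 1.13, and 7 of 12 measured genes were positive and 1 negative (8 and 1 adjusted over the list alone, adjusted p = 0.000401). Odc1 stood at 1.15 ± 0.14 and Slc7a13 at 2.57 ± 0.35. For intercalated cells it was 0.92, and 3 of 6 measured markers were positive (3 adjusted over the list alone, adjusted p = 0.00254). Slc26a4 stood at 2.02 ± 0.16 and Slc4a1 at 2.57 ± 0.36. For kidney protective factors it was 0.85, and 6 of 8 measured genes were positive (6 adjusted over the list alone, adjusted p = 0.000400), with Sirt3 at 1.00 ± 0.12 beside Egf. For cholesterol synthesis it was 0.61, and 5 of 16 measured genes were positive (6 adjusted over the list alone, adjusted p = 0.000904). Cyp51 stood at 1.30 ± 0.21 and Hmgcs1 at 1.14 ± 0.20. The median for thick ascending limb markers was 0.53, and 2 of 6 measured genes were positive (2 adjusted over the list alone, adjusted p = 0.0440). Kcnj1 stood at 1.09 ± 0.19 and Slc12a1 at 1.34 ± 0.28. That for hypoxia and glycolysis was 0.51, and 6 of 15 measured genes were positive and 1 negative (8 and 1 adjusted over the list alone, adjusted p = 0.00357). Pgk1 stood at 0.93 ± 0.13 and Hk2 at -1.21 ± 0.20. That for glutathione, iron and oxidative stress was 0.36, and 3 of 19 measured genes were positive and 1 negative (5 and 1 adjusted over the list alone, adjusted p = 0.0139). Ggt1 stood at 1.45 ± 0.17 and Gss at 0.81 ± 0.14. With an estimated correlation these 11 lists gave adjusted p = 0.162 to 0.436.

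Lists with a negative value are those that rose more in WT. Chemokines and NF-kB targets had a median of -1.90, and 17 of 19 measured genes were negative (18 adjusted over the list alone, adjusted p = 1.33e-14). Il34 stood at -2.10 ± 0.16 and Relb at -1.71 ± 0.15. Tubular injury genes had a median of -1.59, and 12 of 18 measured genes were negative (14 adjusted over the list alone, adjusted p = 8.13e-10), with Cd44 at -2.62 ± 0.22 beside Sox9. Macrophage markers had one of -1.43, and 9 of 12 measured genes were negative (11 adjusted over the list alone, adjusted p = 8.43e-09). Cd68 stood at -1.81 ± 0.21 and C1qc at -1.82 ± 0.22. Matrix genes had one of -1.08, and 13 of 20 measured genes were negative (15 adjusted over the list alone, adjusted p = 7.55e-09). Col6a3 stood at -1.74 ± 0.22 and Col4a2 at -0.94 ± 0.15. Neutrophil markers had one of -0.98, and 2 of 5 measured genes were negative (5 adjusted over the list alone, adjusted p = 0.00357). S100a8 stood at -1.46 ± 0.37 and Csf3r at -0.85 ± 0.22. T and NK cell markers had one of -0.97, and 1 of 6 measured genes was negative (4 adjusted over the list alone, adjusted p = 0.00329). Cd2 stood at -0.96 ± 0.19 and Lck at -1.09 ± 0.32. Fibroblast and pericyte markers had one of -0.93, and 1 of 6 measured genes was negative (3 adjusted over the list alone, adjusted p = 0.00845). Pdgfrb stood at -1.41 ± 0.20 and Pdgfra at -1.24 ± 0.39. Interferon-stimulated genes had one of -0.83, and 10 of 20 measured genes were negative (13 adjusted over the list alone, adjusted p = 2.80e-09). Ddx58 stood at -1.05 ± 0.11 and Oasl2 at -1.33 ± 0.16. As a set interferon-stimulated genes were already higher in KO without IR (median 0.74) and were not called between KO_IR and WT_IR (median -0.063). Cell cycle genes had an interaction median of -0.39, and 2 of 25 measured genes were negative and 1 positive (2 and 0 adjusted over the list alone, adjusted p = 0.000312). Mcm4 stood at -0.83 ± 0.13 and Aurkb at -0.88 ± 0.21. ER stress and amino acid response genes had one of -0.39, and 2 of 14 measured genes were negative and 1 positive (2 and 1 adjusted over the list alone, adjusted p = 0.00845). Trib3 stood at -1.99 ± 0.18 and Asns at -1.08 ± 0.19. The H3K9 and DNA methylation machinery had one of -0.16, and 1 of 19 measured genes was negative (1 adjusted over the list alone, adjusted p = 0.0142). Kdm4a stood at -0.94 ± 0.17 and Setdb1 at -0.45 ± 0.14. With an estimated correlation these 11 lists gave adjusted p = 0.162 to 0.302.

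Single libraries decided some calls of the interaction. The thick ascending limb was not called without WT replicate 1, KO replicate 1, WT_IR replicate 2 or KO_IR replicate 2, ER stress without WT_IR replicate 2 or KO_IR replicate 2, and glutathione without WT replicate 2. Of the 8 fits that leave out 1 library, Havcr1 passed only in those without KO replicate 1 or KO replicate 2, and S100a8 and Csf3r only in that without KO replicate 1. Aurkb was lost without WT replicate 1, KO replicate 1, KO replicate 2, WT_IR replicate 1, WT_IR replicate 2 or KO_IR replicate 2, Slc12a1 without WT replicate 1, KO replicate 1, WT_IR replicate 1 or WT_IR replicate 2, and Cd2 without WT replicate 1, KO replicate 1, KO replicate 2, WT_IR replicate 2 or KO_IR replicate 1. The genes mt-Atp8 and Nccrp1 were lost without KO replicate 1 or WT_IR replicate 2, mt-Atp8 and mt-Co3 without WT replicate 1 or WT_IR replicate 2, and Gss without WT_IR replicate 2.

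**Figure D3:**
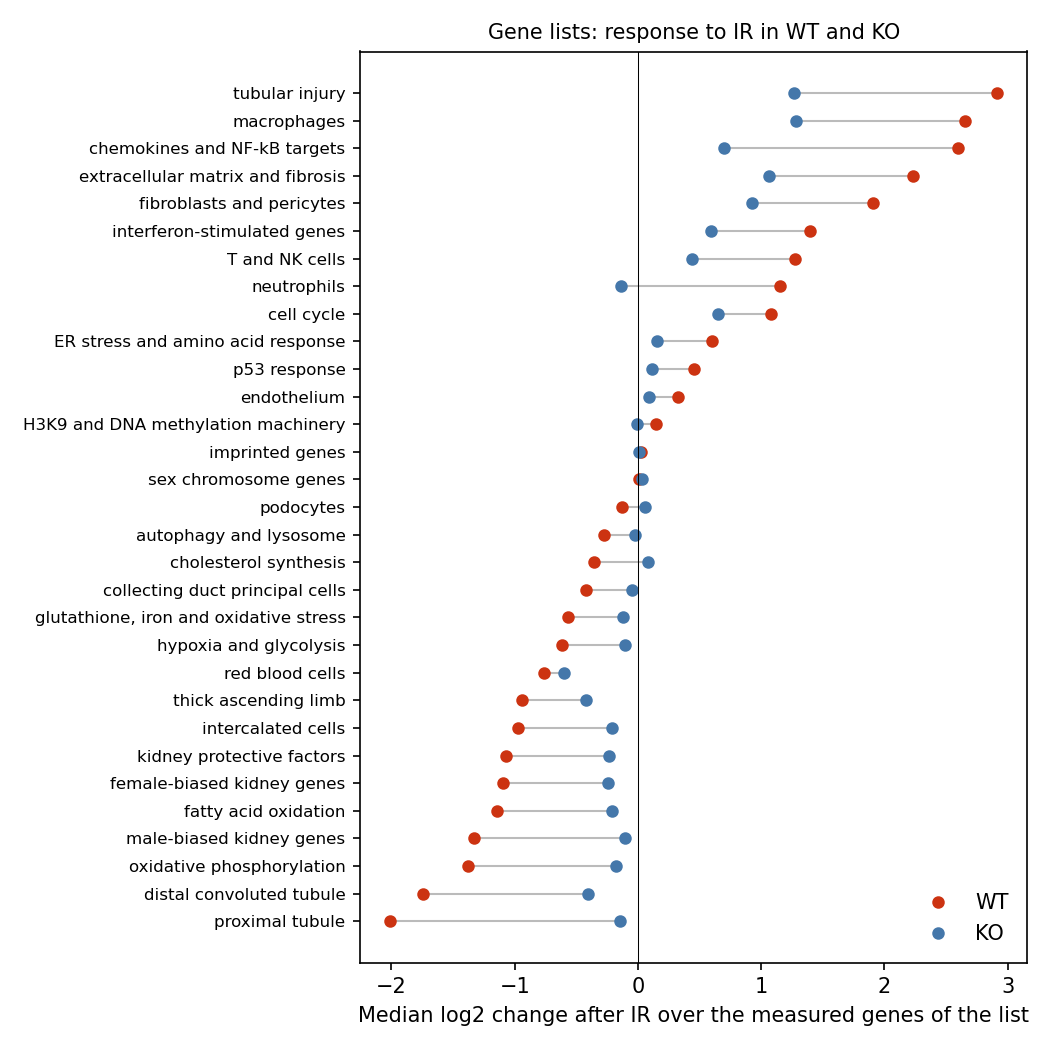
Median log2 change after IR over the measured genes of each list (horizontal axis) in WT (red points) and KO (blue points), with the lists (vertical axis) in the order of the WT value. The tubular injury list stands at 2.91 in WT and 1.27 in KO, and the proximal tubule list at -2.01 in WT and -0.149 in KO.

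The effect of IR averaged over the genotypes picks genes without looking at their difference between WT and KO. It called 5820 genes, 2605 higher and 3215 lower, 829 of them by at least 2-fold. Across these genes, which are not independent replicates, Pearson's r between the responses of WT and KO was 0.833, a value that picking genes by the sum of both responses raises, and the major-axis slope of KO on WT was 0.303. Across genes called by IR in WT r was 0.812, and picking genes by their response in WT can raise this value too. That comparison uses no KO means, but the KO and KO_IR libraries entered the filter and the estimate of spread behind its calls. Across all 15607 tested genes r was 0.659. The slope was 0.234 to 0.381 over the 16 combinations of single libraries. The 2605 rising genes had a median log2 change of 0.91 in WT and 0.30 in KO, and 97.1% of them changed less in KO. The 3215 falling genes had medians of -0.74 and -0.17, and 97.2% of them changed less in KO. By the interaction itself, 977 of the risers and 1443 of the fallers passed with the smaller change in KO, and 5 and 4 with the larger one. On a TPM scale the averaged IR effect called 6004 genes higher and 1340 lower, with a median shift of 0.222.

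The effect of the knockout averaged over both conditions asks what differs between the genotypes with and without IR together. It called 1623 genes higher and 1195 lower in KO, 240 of them by at least 2-fold. Taken apart, the knockout called 34 genes without IR and 4689 after IR. A call by the average thus does not show a difference in both conditions. The count was 1404 without WT_IR replicate 2, 1585 without KO replicate 1, 1673 without WT replicate 2 and 1785 without WT_IR replicate 1. On a TPM scale 1117 were higher and 2962 lower, with a median shift of -0.110.

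**Figure D4:**
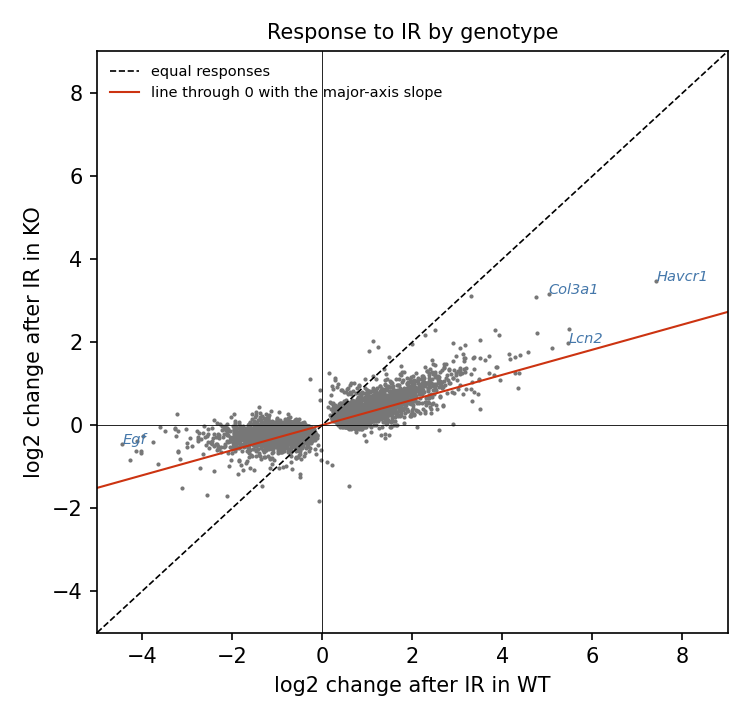
Log2 change after IR in KO (vertical axis) against that in WT (horizontal axis), 1 point for each of the 5820 genes called by the IR effect averaged over the genotypes. The dashed line marks equal responses and the red line, drawn through 0, the major-axis slope of 0.303. Points of rising and falling genes lie nearer to 0 on the KO axis.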

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

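The tests of technical explanations in this part were chosen only after the result was seen, as were the patterns of the clock genes and of KO replicate 2, whereas the interaction was planned.

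The response to IR differed between the genotypes for 2544 genes, for 22 lists and for 109 of the genes named in the report, each by the interaction in limma or, for lists, by camera on it at the preset correlation. With an estimated correlation 0 of the 22 lists were called (adjusted p = 0.162 to 0.436). As the difference subtracts the WT response, noise in the WT and WT_IR libraries alone favours a sign opposite to that response. Such an opposite sign was seen in 107 of these genes and in all 22 lists. The exceptions were Rrm2, with a response of 0.29 ± 0.16 in WT and 1.15 ± 0.16 in KO, and C4b, with 0.29 ± 0.14 and 1.08 ± 0.14 (SE). S100a8 moved in opposite directions, by 0.66 ± 0.26 in WT and -0.80 ± 0.26 in KO, so its change was not a smaller one in KO. The median log2 response in KO minus that in WT was 0.93 for fatty acid oxidation, 1.16 for oxidative phosphorylation, 0.36 for glutathione, iron and oxidative stress, 0.51 for hypoxia and glycolysis, 0.61 for cholesterol synthesis, 0.85 for kidney protective factors, 1.13 for male-biased kidney genes, 1.91 for proximal tubule, 0.53 for thick ascending limb, 1.43 for distal convoluted tubule and 0.92 for intercalated cells. It was -1.59 for tubular injury, -0.39 for cell cycle, -1.08 for extracellular matrix and fibrosis, -1.90 for chemokines and NF-kB targets, -0.83 for interferon-stimulated genes, -0.39 for ER stress and amino acid response, -0.16 for H3K9 and DNA methylation machinery, -0.93 for fibroblasts and pericytes, -1.43 for macrophages, -0.98 for neutrophils and -0.97 for T and NK cells. The thick ascending limb was not called without WT replicate 1, KO replicate 1, WT_IR replicate 2 or KO_IR replicate 2, ER stress without WT_IR replicate 2 or KO_IR replicate 2, and glutathione without WT replicate 2.

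Among single genes, the log2 response to IR in KO minus that in WT was above 3 for Egf 3.98, S100g 3.72, Slc22a8 3.71, Klk1 3.56, Calb1 3.51, mt-Atp8 3.50, Pvalb 3.43, Nccrp1 3.39, Ttr 3.36, Inmt 3.35, Ces1d 3.35 and mt-Co3 3.19. From 2 to 3 were the values of Ces1e 2.98, Cyp2d12 2.63, Miox 2.62, Slc4a1 2.57, Slc7a13 2.57 and Slc26a4 2.02. Lower positive values were Acaa2 1.84, Slc5a2 1.82, Kl 1.59, Ggt1 1.45, Acadm 1.35, Slc12a1 1.34, Cyp51 1.30, Ndufs1 1.28, Sdha 1.22, Aqp3 1.22, Atp5d 1.18, Odc1 1.15, Hmgcs1 1.14, Cycs 1.14, Prr5 1.11, Atp5a1 1.11, Nudt19 1.10, Kcnj1 1.09, Mettl7a2 1.07, Uqcrc2 1.07, Acads 1.06, Alb 1.01, Sirt3 1.00, Aqp1 0.98, Nsdhl 0.95, Idi1 0.94, Pgk1 0.93, Gabarapl1 0.88, Vegfa 0.86, Rrm2 0.86, Akr1c14 0.85, Gss 0.81, C4b 0.79, Hadha 0.77, Snrpn 0.71 and C8a 0.68. The most negative values were Havcr1 -3.95, Lcn2 -3.49, Aoc1 -3.46, Vcam1 -3.25, C3 -3.16, Sox9 -3.13, Ccl2 -3.11 and Cxcl10 -3.02. Then came Prrg4 -2.89, Hspb1 -2.85, Krt20 -2.82, Cp -2.75, Serpina10 -2.70, Serpina3n -2.70, Cd44 -2.62, Tlr2 -2.57, Timp1 -2.54 and Il34 -2.10. Values nearer to 0 were Trib3 -1.99, Col3a1 -1.86, C1qc -1.82, Cd68 -1.81, Col6a3 -1.74, C1qb -1.73, C1qa -1.72, Relb -1.71, Col1a1 -1.67, Cx3cr1 -1.52, S100a8 -1.46, Col1a2 -1.44, Pdgfrb -1.41, Cd79b -1.37, Rtp4 -1.34, Oasl2 -1.33, Oas2 -1.33, Fcer1g -1.32, Slamf9 -1.23, Fcgr1 -1.22, Hk2 -1.21, Fn1 -1.2, Asns -1.08, Ddx58 -1.05, Zbp1 -1.03, Abcc3 -1.03 and Oas1a -1.01. The smallest in size were Col4a1 -0.99, Cd2 -0.96, Kdm4a -0.94, Col4a2 -0.94, Irf7 -0.89, Aurkb -0.88, Csf3r -0.85, Mcm4 -0.83, Ctsd -0.78 and Cdh5 -0.68. Of these genes 28 of 109 ceased to pass in at least 1 of the 8 fits that leave out 1 library. Passing was limited to the fit without KO replicate 1 or KO replicate 2 for Havcr1, without KO replicate 1 for Fn1, Fcer1g, Csf3r and S100a8, without KO replicate 2 for C8a and Rrm2, without KO_IR replicate 2 for C4b and Gabarapl1, without WT_IR replicate 2 for Snrpn, without WT replicate 2, KO replicate 2 or WT_IR replicate 2 for Aqp3, without KO replicate 1 or WT_IR replicate 2 for Cdh5, without WT replicate 2, WT_IR replicate 1 or KO_IR replicate 2 for Cd2, without WT replicate 2 or WT_IR replicate 1 for Aqp1, without WT replicate 2 or KO_IR replicate 1 for Aurkb and without KO replicate 1 or KO_IR replicate 2 for Cd79b. Calls ended for Col3a1 without WT replicate 1, WT_IR replicate 1, WT_IR replicate 2 or KO_IR replicate 1, for Col1a1 and Col1a2 without WT replicate 1 or WT_IR replicate 1, for Nccrp1 without KO replicate 1 or WT_IR replicate 2, for mt-Co3 without WT replicate 1 or WT_IR replicate 2 and for Irf7 and Gss without WT_IR replicate 2. They also ended for mt-Atp8 without WT replicate 1, KO replicate 1 or WT_IR replicate 2, for Ctsd without KO replicate 2 or WT_IR replicate 2, for Abcc3 without WT replicate 1, KO replicate 2 or WT_IR replicate 1, for Slc12a1 without WT replicate 1, KO replicate 1, WT_IR replicate 1 or WT_IR replicate 2 and for Idi1 without WT_IR replicate 1, WT_IR replicate 2 or KO_IR replicate 1.

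The change after IR was smaller in KO than in WT among rising and falling genes alike. A scaling between libraries would move all genes 1 way, and the share of genes with the smaller change in KO was 97.1% among rising and 97.2% among falling genes, which argues against it. Dilution of the injured WT profile with RNA of uninjured kidney would give each list 1 share of the WT change, and the median shares of the extracellular matrix list (30.9%) and the tubular injury list (18.6%), a pair picked after single genes were seen, differed by at least 8.83 points over the 16 combinations of single libraries, which argues against a plain mixture, while the share was 14.2% for chemokines, 33.6% for macrophages, 56.4% for interferon-stimulated genes and 16.6% for the proximal tubule, whose range of 2.51% to 42.8% covers both. An injury of another severity or stage for reasons other than the genotype cannot be told apart from an effect of the knockout. Both predict responses that correlate across the genes called in WT, as these did (r = 0.812, against 0.659 across all tested genes). The labels give no measure of each clamping. A weaker or earlier resolved injury through the knockout may thus be 1 of several explanations.

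Clock genes differed between KO and WT without IR: all 5 genes of the activator phase were lower in KO (median log2 difference -1.03) and all 12 of the repressor phase higher (0.72), while Ciart alone of the 17 passed the test. A harvest at another hour of the day may account for this, since the difference between the 2 WT libraries, which share the genotype, lay on the same axis, with Pearson's r = 0.733 across these genes, which are not independent. The median difference of WT replicate 1 minus WT replicate 2 was -0.78 in the activator and 0.73 in the repressor set. A change of the clock by the knockout itself cannot be told apart, since the lowest WT value of Arntl was 3.75 times the highest KO value and no series over the day is used here.

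Injury transcripts were higher in KO replicate 2 than in KO replicate 1: of 20 genes under 1 FPKM in both WT libraries and over 10 FPKM in WT_IR, picked without the KO libraries, 18 were higher. Carry-over of RNA or reads from an injured WT library would add 1 share of its profile, and after the best share of 3.13% the median residual was 2.08 times the median difference between the WT libraries (1.71 to 2.39 with any 1 gene left out). For carry-over from an injured KO library the best share was 13.0% and the residual 2.10 times that difference (1.62 to 2.31). A bound of 2 on the value itself was written first and would exclude both sources, whereas that it must hold with any 1 gene left out, and the present picking of genes, came after values of 1.84 and 2.27 on 17 genes had been seen. As both ranges reach below 2, carry-over and an injury in a pooled mouse, for which no biological explanation was tested, cannot be told apart.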

How the results depend on the processing

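In this part the fits without both KO replicate 2 and KO_IR replicate 1, with a block within genotype and with a clock index were chosen only after seeing the data, and all other alternatives were planned.

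Leaving out each library in turn gave 4781 to 6554 genes for IR in WT, 0 to 109 for IR in KO, 0 to 17 for the knockout without IR, 2612 to 4557 for the knockout after IR, 1289 to 2315 for the interaction, 4474 to 5194 for IR averaged over the genotypes, 1404 to 2352 for the knockout averaged over injury, 132 to 140 list calls, and a slope of 0.277 to 0.355. The value of 0 for IR in KO came in limma without WT_IR replicate 1, WT_IR replicate 2 or KO_IR replicate 1, and the value of 0 for the knockout without IR without WT replicate 1 or KO replicate 1. The WT_IR libraries do not enter the KO_IR minus KO estimates, which kept a median shift of 0 without either of them. In those fits only the shared estimate of spread and its degrees of freedom differed. For the other fits the cause was not tested, and they also have fewer degrees of freedom. Without KO replicate 2 and KO_IR replicate 1 together the counts were 23 for IR in KO, 0 for the knockout without IR (1426 at an unadjusted p under 0.05), 2484 for the knockout after IR, 497 for the interaction and 1144 for the averaged knockout effect, and the slope was 0.401.

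A change of at least 2-fold was met by 2203 genes for IR in WT, 92 for IR in KO, 1138 for the knockout after IR, 1150 for the interaction, 829 for averaged IR and 240 for the averaged knockout effect. With a minimum mean of 5 FPKM, which tests 7728 genes, the counts were 4234 for IR in WT, 16 for the knockout without IR and 3843 for averaged IR. Without a filter they were 35 for IR in KO, 19 for the knockout without IR and 1670 for the interaction, with 29649 genes tested. Only the 2 groups of a comparison in the limma fit gave 0 for IR in KO (1806 unadjusted) and 0 for the knockout without IR (1755 unadjusted). With voom on recovered fragments the counts were 314 and 61 for these comparisons. For the knockout without IR a pseudocount of 5 gave 7, quantile normalization 0 (1757 unadjusted), and a clock index as a covariate 0 (1051 unadjusted). That covariate gave 176 for the knockout after IR and 2184 for the interaction, of which 2038 were among the 2544. Over the 34 genes called without IR the median size of the log2 change was 1.2 before and 1.17 with the covariate and the median SE 0.136 and 0.231. Over the 4689 called after IR these were 0.69 and 0.60, and 0.125 and 0.234, so these calls ended mostly through wider errors, as the index itself differs between the genotypes. With libraries on a TPM scale 7530 genes passed for the knockout after IR and 4823 for the interaction, and the share with the smaller change in KO was 98.8% among rising and 95.6% among falling genes. The cause was not tested for the pseudocount, quantile, voom and TPM values. With an estimated correlation 0 of 137 list calls held in camera.

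The replicate number as a block gave 9 genes for the knockout without IR, 6402 for IR in WT, 175 for IR in KO, 4576 for the knockout after IR and 2473 for the interaction, and a block within genotype 6554 for IR in WT, 182 for IR in KO, 2671 for the interaction and 5845 for averaged IR. Across all tested genes the deviations from the group mean under equal numbers had an r of -0.122 to 0.164 between groups. Across the 17 clock genes the difference of replicate 1 minus 2 had an r of 0.886 between WT and WT_IR and of -0.0923 between KO and KO_IR, so a pairing of the WT libraries, such as a shared harvest hour, stays open.

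A few genes turned direction with the scaling, each without passing the test. Under quantile normalization the log2 change of Lamp1 was 0.086 for IR in WT, -0.029 for the knockout after IR and -0.058 for the interaction, and that of Gabarap 0.18 for IR in WT. For IR in WT on a TPM scale it was 0.11 for Gabarap, 0.0086 for Igf2r and 0.067 for Scnn1g. The cause was not tested. Counting each named gene and each alternative, 13626 values kept direction and side of the threshold, 920 no longer passed and 125 came to pass. For lists these numbers were 2988, 199 and 48, with 0 turned.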

Other observations

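The gene groups of the next 3 paragraphs were chosen only after their values were seen, and the splits of the libraries were planned.

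Mitochondrially encoded transcripts, which code for subunits of the respiratory chain, fell in WT after IR with the nuclear genes of oxidative phosphorylation. Their share of all fragments was 7.82% and 8.53% in the WT libraries, 7.99% and 8.06% in KO, 3.99% and 4.15% in WT_IR and 7.54% and 7.08% in KO_IR. The log2 changes of 7 abundant ones, mt-Co1, mt-Cytb, mt-Nd1, mt-Nd2, mt-Nd4, mt-Nd5 and mt-Nd6, for IR in WT were -1.17 to -1.66. For IR in KO they were -0.045 to -0.28, and none passed in limma. The interaction passed for 6 of the 7, with mt-Nd2 at 1.38 ± 0.27 (SE, adjusted p = 0.0161), and did not for mt-Co1 (0.99 ± 0.34, adjusted p = 0.0994). Nuclear copies of mitochondrial sequence exist, so reads can be shared between them.

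Of 17 clock genes 12 were called between KO_IR and WT_IR and 1 between KO and WT. The difference was larger in size after IR for 13 of them, and the interaction passed for 1, Hlf (1.66 ± 0.28, adjusted p = 0.0103). Dbp, an output gene of the clock, stood at 20.5 and 6.29 FPKM in WT, 50.6 and 51.0 in KO, 8.23 and 2.94 in WT_IR and 43.3 and 38.5 in KO_IR. Hlf changed by -1.95 ± 0.20 (adjusted p = 0.000319) with IR in WT and differed by 2.19 ± 0.20 (adjusted p = 0.000591) between KO_IR and WT_IR. Arntl, an activator of the clock, differed by -1.07 ± 0.31 after IR (adjusted p = 0.0364), and Nfil3 by -1.63 ± 0.36 (adjusted p = 0.0138).

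Immediate early genes, which respond within minutes to stress or handling, set KO_IR replicate 1 apart from KO_IR replicate 2. Of 14 such genes all but Egr2, listed at 0 in every library, were higher in replicate 1 (13), with a median log2 difference of 2.09. Nr4a1 stood at 30.5 against 1.64 FPKM, Atf3 at 60.2 against 3.72 and Cyr61 at 203 against 18.9. In the other groups the median difference between the replicates was 0.14 in WT, -0.19 in KO and -0.16 in WT_IR.

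In a fit of 2 groups of 4 libraries, IR against no IR called 562 genes, and each other split of the 8 libraries at most 1, so that 1 of the 35 splits, the real one, gave as many, which argues against a random split as the source of that count. The split by genotype called 1 gene, 4 of the 35 splits gave at least as many, and the highest of the others was 562, for the split by IR, so a random split is not excluded for the genotype in this fit. The split by IR calls many times the genotype's count and marks a structure of the samples, which the fit with 4 group means takes out and this one does not.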
